A study of Caenorhabditis elegans with 6 samples.

How the data were processed

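ATAC-seq was carried out on nuclei of the strain OH11061, which carries otIs381, in 3 samples of neuronal nuclei (GFP and DAPI positive) and 3 samples of total nuclei (DAPI positive), with 50000 nuclei in each. Samples were grouped by the labels. Nothing in the labels says whether the samples of a group came from separate cultures.

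Reads were processed with cutadapt 1.9.1, Bowtie2 2.2.6, SAMtools 1.7, Picard, bedtools 2.26 and MACS2 on build ce11, per the submitters' processing notes, which name no role or parameter. Whether reads were shifted for the Tn5 cut, how duplicates were treated and whether mitochondrial reads were removed are not given in the sources used here. The authors deposited 1 narrowPeak list per group, and its name gives a threshold of 0.1 on the irreproducible discovery rate (IDR), which keeps peaks that rank alike in repeated calls. How the samples were combined is not given in the sources used here, nor is the meaning of "ppr" in the names of the lists. The lists keep only reproducible peaks, so a site missing from a list is not shown to be closed. Reproducible here may not mean reproducible across samples.

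Each peak has a deposited score, a scaled IDR value from 415 to 1000. It was 1000 in 2084 neuronal (90.1%) and 2414 total peaks (90.0%). The deposited fold enrichment of each peak is a ratio to the local background from the authors' peak caller, with a median of 10.5 in the list labelled neuronal (range 1.30 to 51.5) and 10.7 in the list labelled total (1.26 to 51.9). The deposited −log10 p-value, also from the authors' peak caller, had medians of 1178 and 749.0. It grows with depth and was used to rank peaks within a list and, with the fold, to recover pileups. The deposited summit offset gave the position of each summit. Median peak widths were 799 bp and 823 bp, and the lists covered 2103 kb and 2461 kb. No peaks overlapped within a list. Fold was under 2 for 5 neuronal peaks, all with a score of 1000, and for 9 total peaks, 7 of them with that score.

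Overlaps, tests and intervals were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9. A peak was shared if it overlapped the other list by at least 1 bp. Chance overlap came from 1000 random placements of each list, chromosome and width kept. Shares have exact binomial 95% intervals, which cover counting error only, and the limit for a count of 0 is 3 counts of the total. Classes were compared with two-sided Fisher's exact tests, with odds ratios after adding 0.5 to each cell. Ranks of shared peaks were compared with two-sided permutation tests of 100000 resamples. The threshold was 0.05, on p adjusted by Benjamini-Hochberg over the lists where lists were tested. Peaks and genes are not replicates.

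Gene positions came from a table of 19971 protein-coding genes of the assembly WBcel235, the same sequence as ce11, with start and end but no strand, exons or transcripts. The plan, fixed before the data were examined, assigned peaks to the nearest 5′ end, which needs strand. Peaks were therefore assigned to the gene with the nearest end of either kind, and "near a gene end" includes 3′ ends. Exon, intron and UTR positions were not analysed here. The planned 15 motif tests need a genome sequence and were not run. The plan named bedtools for the overlaps, which were computed in Python instead. Of 687 members of the 16 gene lists, 672 matched the table. The 16 lists (8 neuronal, 7 of other cell types and 1 of ribosomal and ubiquitous genes) were fixed before the data were examined.

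Named genes followed a rule fixed before the data were examined. It takes the 10 genes with the highest fold for each class of list-only peak, the 5 with most such peaks in each class, and up to 4 members per list in its more frequent class, besides ric-19 and rab-3. Since no gene had more than 1 neuronal-only peak, the second part named 5 of the first 10 genes again. Other members of a list are named to complete a small count, or as examples chosen after their values were seen.

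Alternatives covered the overlap that counts as shared, stronger peaks alone, equal numbers of peaks, the gene end window and the assignment to genes. Added after seeing the data were assignment to the nearest gene span, the 8 neuronal lists as 1 list, the share of each list with any peak, and leaving out peaks of fold under 2. The pileup (reads over the summit) and local background of each peak were also recovered after seeing the data, by solving the peak caller's fold formula and Poisson tail for both. Pileups came out whole within 0.02 for 99.8% of neuronal and 99.9% of total peaks. This recovery assumes default MACS2 formulas. The list tests and the recovery were tested on simulated data. In 1600 list tests with nothing planted there were 0 calls, and 300 of 300 made pileups were found. The tests that weigh explanations in the closing section were revised after results were seen: a first version of 7 tests was run and then replaced by 5, of which 2 were dropped because the choice of what they measured fixed their outcome.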

Results

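Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in nuclei from mixed-stage Caenorhabditis elegans populations made up mostly of larvae. The animals carried the transgene otIs381, a reporter that puts GFP into the nuclei of neurons. Nuclei sorted as positive for both GFP and the DNA stain DAPI form the neuronal group, with 3 samples, and nuclei sorted on DAPI alone form the total group, also with 3 samples. Each sample held 50000 nuclei. The deposited data used here are 2 peak lists, 1 per group, of 2313 peaks for neuronal nuclei and 2683 peaks for total nuclei on build ce11. No value per replicate was analysed here, so no statement below rests on a spread between replicates, and each test compares these 2 lists and not the conditions. Read depth per sample is not given in the sources used here.

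The highest peak of both lists was found next to ric-19, a gene active across the nervous system that acts in dense-core vesicle maturation. This peak lay on chromosome I from 3781476 to 3781920 in the list labelled neuronal, 35 bp outside the gene (CELE_C32E8.7), with an authors' fold enrichment of 51.5 over local background. In the list labelled total it ran from 3781476 to 3781914, with a fold enrichment of 51.9. The next highest fold was 26.4 in the list labelled neuronal and 28.2 in the list labelled total, both near B0294.3 on chromosome X. The ric-19 promoter drives the sorting reporter, so reads from the transgene and from the gene's own locus cannot be separated in these values. No peak was assigned to rab-3, which encodes a synaptic vesicle GTPase and is used as a pan-neuronal marker.

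The comparison of neuronal with total nuclei asks which sites are open in neurons relative to the whole animal. Nuclei sorted on DAPI alone include those with GFP, so the total group holds neuronal nuclei too, and some overlap is built into the design. Of the 2313 peaks in the list labelled neuronal, 2218 overlapped a peak of the list labelled total by at least 1 bp, a share of 95.9% (95% exact binomial interval 95.002% to 96.7%). In the other direction 2216 of 2683 peaks were shared, or 82.6% (81.1% to 84.01%). Shared peaks included those of the kinesin gene unc-104, the syntaxin gene unc-64, the vesicular monoamine transporter gene cat-1 and the intestinal GATA factor gene elt-2. This left 95 peaks in the list labelled neuronal alone and 467 in the list labelled total alone. When peaks were placed at random on their chromosomes, on average 115.8 of either list overlapped the other, 5.00% of the neuronal and 4.32% of the total list. The intervals cover counting error only.

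Sites found in both lists coincided closely. Among 2199 peaks paired one to one, the median distance between summits was 0 bp, 1154 pairs (52.5%) had the same summit and 87.4% lay within 10 bp. Across these peaks, which are not independent replicates, the ranks by fold enrichment had a Spearman correlation of 0.976.

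Peaks of 1 list alone were weak by the authors' p-value, but not all were weak by fold. By the authors' p-value, 92 of the 95 neuronal-only peaks (96.8%) and 355 of the 467 total-only peaks (76.02%) lay in the weakest 20% of their list, and none lay in its stronger 50%. The median fold enrichment of neuronal-only peaks was 7.63 against 10.7 for the shared peaks of the same list. For total-only peaks it was 8.16 against 11.3. The highest folds among neuronal-only and total-only peaks, 12.4 and 12.8, lay above the medians of their lists, 10.5 and 10.7.

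**Figure D1:**
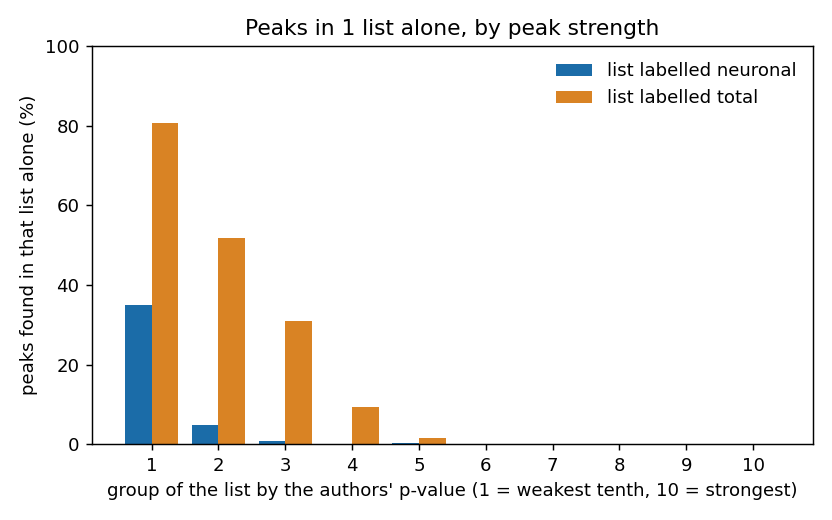
Share of peaks found in 1 list alone (percent, vertical axis) in each of 10 equal groups of that list, ordered by the authors' p-value from the weakest (1) to the strongest (10), with blue bars for the list labelled neuronal and orange bars for the list labelled total. In group 1, 35.1% of neuronal and 80.6% of total peaks were in 1 list alone, and no bar rises above 0 in groups 6 to 10.

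The neuronal-only peak with the highest fold enrichment, 12.4, lay 835 bp from F16G10.6 on chromosome II (2378353 to 2379059). It was followed by peaks near C31H1.2 (fold 10.6, 12825 bp away), the nuclear hormone receptor gene nhr-131 (10.2, inside the gene, on chromosome V from 494206 to 495084), F43E12.1 (10.2) and a gene model on chromosome IV 2021 bp from its peak at 15793113 to 15793727 (10.1). The remaining 5 of the 10 highest, near Y55F3AM.11, Y73F8A.22, Y57G11C.38, the myosin gene hum-5 and mltn-11, had folds from 9.86 to 10.1. No gene had more than 1 neuronal-only peak. None of these 10 genes belongs to the neuronal lists.

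The total-only peak with the highest fold enrichment, 12.8, lay 604 bp from unc-36, which encodes a calcium channel subunit, on chromosome III (8201543 to 8202141). The peaks near rgs-1, a regulator of G protein signalling (12.4), C48D5.3 (12.4), vang-1, a planar cell polarity gene (12.3), and lron-8 (11.8) came next. The others of the 10 highest lay near C16C8.18, gly-13, tag-273, the helix-loop-helix gene hlh-33 and Y53G8AR.8, with folds from 11.4 to 11.7. Of 457 genes with a total-only peak, 10 had 2 of them. The leading genes among those were isw-1 (a chromatin remodeller), frl-1, mdt-27 (a Mediator subunit), aakg-1 (a subunit of AMP-activated kinase) and W02B3.3. At isw-1 the peak of higher fold (11.4) lay inside the neighbouring gene rbf-1, a member of the pan-neuronal list, but nearer to an end of isw-1.

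Relative to genes, 59 of 95 neuronal-only summits (62.1%, exact interval 51.6% to 71.9%) and 322 of 467 total-only summits (68.95%, 64.5% to 73.1%) lay near a gene end, from 1000 bp outside to 200 bp inside. The odds ratio was 0.735 (95% interval 0.466 to 1.16; two-sided Fisher's exact test over peaks, p = 0.228). Among shared peaks of the list labelled neuronal the share was 60.9%, and at random positions it was 36.1%. With a window of 500 bp outside and 100 bp inside, the shares were 44.2% and 61.5% and the difference passed the threshold (Fisher's exact test, p = 0.00283). A window of 2000 bp and 500 bp gave 69.5% and 81.2% (Fisher's exact test, p = 0.0128).

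The X chromosome held 15 of 95 neuronal-only peaks (15.8%, exact interval 9.12% to 24.7%) and 57 of 467 total-only peaks (12.2%, 9.38% to 15.5%), with an odds ratio of 1.37 (0.747 to 2.53; two-sided Fisher's exact test, p = 0.399). Of the shared peaks of the list labelled neuronal, 20.6% were on X (18.9% to 22.3%). X holds 13.7% of the protein-coding genes and 17.7% of the genome's length. Chromosome IV held 26.3% of the neuronal-only and 15.4% of the total-only peaks, a difference that was not tested.

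No member of the fixed neuronal gene lists was among the genes with neuronal-only peaks, and a few were among those with total-only peaks. The test could not pass for so few members. Of 354 members of 8 neuronal gene lists, none was among the 94 genes with neuronal-only but no total-only peaks, which allows a share of up to 3.19%. Among the 456 genes with total-only but no neuronal-only peaks 12 were members (2.63%; two-sided Fisher's exact test, p = 0.235). A neuronal-only count of 0 is the lowest possible, so with 12 members this test could not pass in that direction and decides nothing. With peaks called shared when summits lay within 100 bp, unc-31 was a neuronal-only member, and with equal numbers of peaks fmi-1 was. By the 1 bp rule on the full lists the peaks of both genes were shared. The equal-numbers setting drops weak peaks of the list labelled total, which left the fmi-1 peak without its partner. The union of the 8 lists was formed after the values were seen.

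The pan-neuronal list, with genes of synaptic vesicle release and neuronal transport, had 6 total-only members. These were unc-13 (a vesicle priming factor, fold 11.003, on chromosome I from 7421155 to 7421669), aex-3 (9.91), egl-3 (a proprotein convertase that processes neuropeptides, 8.49), maco-1 (7.89), the synaptobrevin gene snb-1 and the endophilin gene unc-57. It had 0 neuronal-only members (two-sided Fisher's exact test, p = 0.596, adjusted p = 1). No lower count was possible, so with 6 members this test could not pass in that direction either. The channel list had unc-36 (12.8) and unc-79 (10.5), the ciliary list dyf-3 (9.18) and ift-81 (8.65), the transcription factor list unc-39 (5.56) and the axon guidance list zig-1 (7.94), all total-only. At unc-39 a further peak was shared. The ift-81 peak lay inside ags-3. The neurotransmitter, neuropeptide and chemosensory lists had no member in either class.

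Lists of other cell types had 3 neuronal-only members, unc-68, glh-1 and lit-1, and the difference from the neuronal lists was not tested. The body-wall muscle list had the ryanodine receptor gene unc-68 (fold 9.17) as neuronal-only and act-4, mlc-2, mup-2 and unc-15 as total-only, with a further shared peak at act-4. The germline list had glh-1 (6.46) as neuronal-only and syp-2 as total-only, and the glial list lit-1 (4.97) and hlh-32 (both lists p = 0.313, Fisher's exact test). At lit-1 another 2 peaks were shared. The cuticle collagen gene col-120 (7.99) was total-only. Ribosomal and other ubiquitous genes had 4 total-only members, hsp-1, rpl-13, rpl-19 and rps-29, of which rps-29 rested on a peak of fold 1.35. The pharynx, intestine and coelomocyte lists had no member in either class. Adjusted by Benjamini-Hochberg over the 16 lists, every p was 1. Simulated data of this size held genes drawn at random from all protein-coding genes, with members of the neuropeptide list planted among the neuronal-only genes. With 5 planted, that list was called in 92 of 100 runs, and with 3 in 12 of 100. The pan-neuronal list, which had 6 total-only members, was not planted, so these rates may not hold for it. No members were planted among the total-only genes alone. For lists with 0 neuronal-only members, an excess there could not be called at the counts seen.

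Pan-neuronal, ribosomal and muscle genes carried peaks more often than other genes. This comparison was added after the values were seen, and genes were not matched on length, so an effect of gene length is not excluded. A peak in either list was assigned to 22 of 36 pan-neuronal genes (61.1%), against 12.8% of all other protein-coding genes (odds ratio 10.5, 95% interval 5.44 to 20.4; two-sided Fisher's exact test, adjusted p = 2.56e-10). Among them were unc-104, unc-31, unc-33, unc-51, unc-64, unc-119, snn-1 (synapsin) and syd-2. The ribosomal and ubiquitous list followed with 26 of 65 (40%; Fisher's exact test, adjusted p = 3.42e-07) and body-wall muscle with 12 of 41 (29.3%, adjusted p = 0.0240). When only summits near a gene end were assigned, the order of the first 2 lists turned, with 47 of 65 ribosomal and ubiquitous genes (72.3%) and 13 of 36 pan-neuronal genes (36.1%), and the muscle call was lost (Fisher's exact test, adjusted p = 0.0731). With gene spans widened by 2000 bp the shares were 80% and 72.2%.

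The other lists did not pass with peaks assigned to the nearest gene end. Peaks were assigned to 11 of 50 axon guidance genes, 11 of 59 channel genes, 6 of 38 ciliary genes, 5 of 60 neuronal transcription factor genes, 3 of 35 chemosensory genes, 2 of 56 neuropeptide genes (flp-23 and nlp-4) and 1 of 20 neurotransmitter genes (cat-1). For channel genes the direction turned, and the test was passed, when only summits near a gene end were assigned (1 of 59, or 1.69%, against 13.3% of other genes; Fisher's exact test, adjusted p = 0.0188). The remaining lists had 7 of 50 for germline, 4 of 50 for intestine, 4 of 54 for cuticle, 3 of 18 for glia, 0 of 26 for pharynx and 0 of 14 for coelomocyte and excretory genes. Counted per peak list, 16 pan-neuronal genes had a peak in the list labelled neuronal and 22 in the list labelled total, while over all protein-coding genes the numbers were 2167 and 2485.

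**Figure D2:**
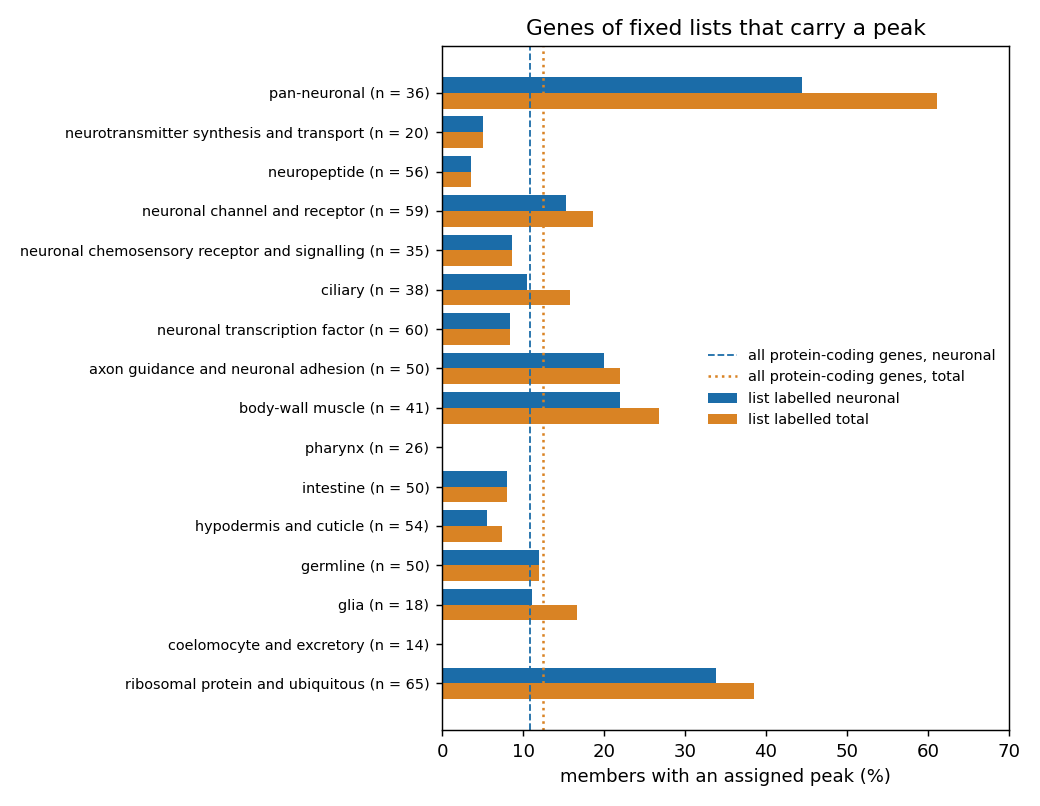
Share of the members of each fixed gene list that have an assigned peak (percent, horizontal axis; n is the number of members), with blue bars for the list labelled neuronal, orange bars for the list labelled total, and lines at the share over all protein-coding genes (10.9% dashed, 12.4% dotted). With peaks assigned to the nearest gene end, as drawn, pan-neuronal genes stand highest at 44.4% and 61.1%, but over both lists ribosomal and ubiquitous genes stood higher near a gene end alone (72.3% against 36.1%) and with spans widened by 2000 bp (80% against 72.2%).

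Among the shared peaks, ranked by fold and assigned to the nearest gene end, no fixed list passed the test, and neuronal lists lay on both sides of 0. Ranks by fold enrichment were taken among the same 2199 shared peaks and compared as percentiles, neuronal minus total. Each difference given is the mean over a list's peaks minus the mean over all other shared peaks. For the 19 pan-neuronal peaks it was -1.51 percentile points (permutation test, p = 0.299, adjusted p = 0.532). Their own neuronal minus total differences had an SD of 7.09, and 11 of 19 were lower in the list labelled neuronal. With only summits near a gene end assigned, the difference was -5.60 over 10 pan-neuronal peaks, 9 of them lower (permutation test, p = 0.00764, adjusted p = 0.0611), and ranked by p-value it was -3.23 over 19 (permutation test, adjusted p = 0.168). Mean differences were also below 0 for ciliary (-5.35, 4 peaks), body-wall muscle (-3.67, 9 peaks), channel (-2.98, 11 peaks), axon guidance (-2.45, 10 peaks) and cuticle genes (-2.06, 3 peaks). They were above 0 for chemosensory (5.66, 3 peaks), glial (4.89, 3 peaks), neuropeptide (4.60, 2 peaks), neurotransmitter (2.09, 1 peak), ribosomal and ubiquitous (1.95, 22 peaks), neuronal transcription factor (1.80, 5 peaks), intestinal (1.59, 4 peaks) and germline genes (1.38, 5 peaks). The lowest adjusted p over these lists was 0.461 (permutation test). Ranked by p-value instead, the 8 neuronal lists together passed at -2.59 (permutation test, p = 0.0116, 55 peaks). By fold they did not pass, at -1.30 with the nearest gene end (permutation test, p = 0.134), nor under other assignments or overlap rules (permutation tests, p from 0.0853 to 0.245). The pharynx list passed at 26.2 with 1 peak, assigned to phat-4 on chromosome V from 4131277 to 4132033, under 2 other assignments (permutation test, adjusted p = 0.0435). By nearest gene end this peak belongs to nhr-57, which is in no pharynx list, so the result is the rank of 1 peak. Peaks are not replicates, and these values describe the 2 lists.

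**Figure D3:**
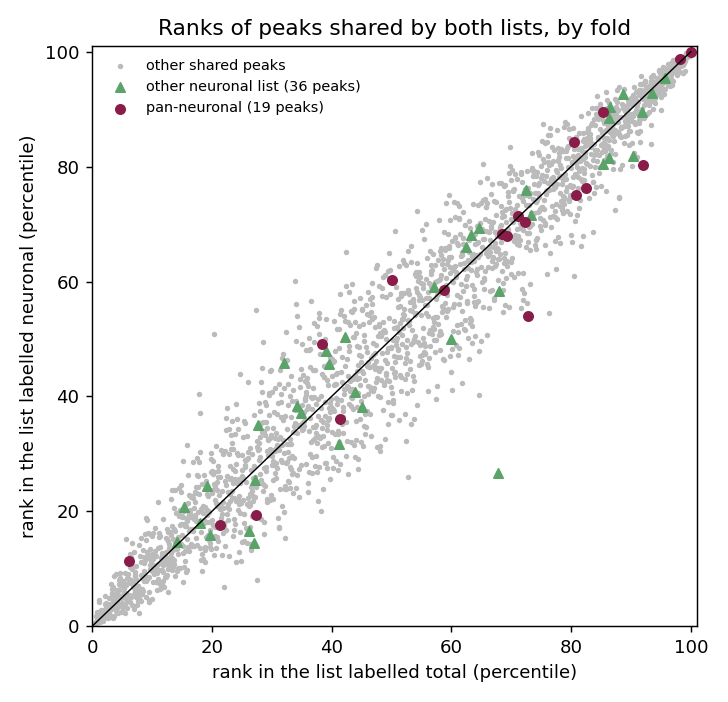
Percentile rank by the authors' fold enrichment of each of 2199 shared peaks among the shared peaks of the list labelled total (horizontal axis) and of the list labelled neuronal (vertical axis), with pan-neuronal genes as dark red circles and the other neuronal lists as green triangles. Points lie along the line of equal rank (Spearman correlation 0.976), and pan-neuronal peaks fall on both sides of it.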

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

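Tests under assignment to the nearest gene span, of the 8 neuronal lists as 1 list, of the share of a list with any peak, and without peaks of fold under 2 were chosen after the results were seen. No paired analysis was possible because the deposited lists hold no value per replicate, and for the same reason no sample was left out in turn. Of 260 results under alternatives, 227 were unchanged, 17 reversed, 11 moved, 4 were stronger and 1 weaker. Unchanged means the same direction and side of the threshold, a share within its interval, or a count changed by less than 1.5 times. Of the 227, 93 were differences in list share, which rest on few genes and passed the threshold in no setting, so they say little about stability. Leaving out peaks of fold under 2 changed no call. Merging had nothing to merge, the list-only peaks from the stronger part of each list (0 and 0) left no share to test, and alternatives for motifs were not run. The cause of a change was not tested unless given.

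The neuronal share of shared peaks was 94.5% with reciprocal overlap, 97.9% for the stronger 50% of each list and 92.0% with equal numbers of peaks. The total share was 84.4% and 91.7% under the last of these 2 settings. List-only counts were 24 and 210 for the stronger 50%, and 186 and 191 with equal numbers, where the larger list loses its weak peaks by construction. The 24 and 210 also arose by construction. Each of these peaks overlapped a peak of the other full list, which lay in the weaker part left out. The difference in gene end share (neuronal minus total) passed the threshold at -17.2 points with the narrow window, -11.7 with the wide window and -9.84 with equal numbers, with p from 0.00283 to 0.228 over all settings.

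Differences in list share, all with an adjusted p of 1, reversed for ribosomal and ubiquitous genes at 0.403 (span plus 2000 bp), 0.130 (reciprocal overlap) and 3.87 (stronger 50%). They reversed for muscle at -0.550 (near an end), -0.481 (stronger 50%) and -0.523 (equal numbers), and for axon guidance at 0.546 (equal numbers). Each rests on a few genes. For pan-neuronal genes it was -0.33 with summits within 100 bp against -1.32, where unc-31 became neuronal-only.

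The excess of genes with any peak reversed for ciliary genes at -4.94 (nearest span) and -0.102 (near an end), channel genes at -11.6 (near an end, Fisher's exact test, adjusted p = 0.0188) and -2.35 (span plus 2000 bp), axon guidance at -3.27 (near an end), glia at -13.3 (near an end) and -4.32 (span plus 2000 bp), and germline at -0.988 (span plus 2000 bp). For muscle it was 13.6 near an end, past the threshold no longer. For pan-neuronal genes it was 22.9 near an end against 48.3, with adjusted p from 1.93e-11 to 0.00358, and for ribosomal and ubiquitous genes 59.2 near an end and with the wider span against 27.2, with adjusted p from 2.73e-26 to 3.42e-07 (Fisher's exact tests). Rank differences reversed for neuropeptide genes at -1.12 (span plus 2000 bp) and germline genes at -0.0684 (nearest span). Ranked by p-value, the 8 neuronal lists together differed by -2.59 (permutation p = 0.0116), lower in the list labelled neuronal. The pharynx list, with no shared peak under the nearest end, had 1 near an end or with the wider span, at 26.2 (permutation test, adjusted p = 0.0435). The nearest gene end to this peak is that of nhr-57.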

Other observations

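All tests in this part were chosen after the results were seen, and those that weigh explanations were revised. A first version of 7 tests was run, and its values were known when 5 tests replaced it, of which 3 are kept and 2 were dropped because the choice of what they measured fixed their outcome. The thresholds of the 3 tests were therefore not chosen blind. The first version gave percentiles of 12.3 for the 8 neuronal lists together, 10.2 with matching on pileup and 15.2 with matching on gene length, none past its limit. It put ric-19 at 4.66 times the next highest pileup among peaks of lower background, but at 1.19 times over all peaks, which met its own condition against extra copies.

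Recovered pileups at the 2199 shared peaks, scaled by each list's lowest background and centred on their median, give a ratio of the 2 lists. Its SD over peaks was 0.113 on the log2 scale against 0.051 for counting alone, and 32 peaks lay beyond 0.3 in either direction. Highest in the list labelled neuronal were F44E5.4 (0.40, chromosome II from 11759141 to 11759695), rsd-3 (0.38) and C01B9.1 (0.38). Lowest were cab-1 (-0.47, chromosome X from 12205337 to 12206046), the potassium channel gene slo-1 (-0.47), stn-1 (-0.46) and K10G9.2 (-0.39). Among the 25 lowest were peaks of 5 genes of the neuronal lists, slo-1, sax-7, unc-31, unc-44 and unc-26, and among the 25 highest 0, while 55 of all 2199 belonged to those lists. Without replicates these ratios have no error across samples.

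By list, the medians of this ratio went both ways, but the neuronal lists below 0 lay further from random lists than those above. Of the 8 neuronal lists, 3 lay below 0: pan-neuronal (-0.08, 19 peaks, percentile 0.68 of 10000 random lists of the same size), ciliary (-0.15, 4 peaks, percentile 0.65) and axon guidance (-0.08, 10 peaks, percentile 3.12). The other 5 lay above 0, at percentiles from 56.2 to 89.4. Their medians were 0.07 for transcription factor (5 peaks), 0.06 for neuropeptide (2), 0.02 for chemosensory (3), 0.02 for neurotransmitter (1) and 0.01 for channel genes (11). Glial genes had 0.14 over 3 peaks (percentile 97.8), intestinal genes 0.09 over 4 (percentile 94.3) and muscle genes -0.07 over 9. The 8 neuronal lists together lay at -0.02 (percentile 12.3) and the 7 lists of other cell types together at -0.04 (percentile 5.28). Percentiles are not corrected for the number of lists. Of 3 sets picked by gene name after the ratios were seen, histone genes had the highest median of any set or list, 0.20 over 6 peaks, heat shock genes had 0.13 over 6, and unc- genes outside the neuronal lists had -0.05 over 22. Percentiles are not given for these sets, since their choice from the same ratios would fix them.

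Peaks of neuronal genes showed no common rise in the list labelled neuronal, as the medians above give. Lower depth of that list is argued against, since its lowest background was 1.60 times that of the list labelled total. An exchange of the list names could account for the low pan-neuronal median, but would put muscle genes high. The muscle median lay at percentile 6.89, past neither limit. Muscle was the only other cell type used in this test. Glial (percentile 97.8), intestinal (94.3) and germline genes (77.1) lay above 0, cuticle genes (26.9) below it, and the 7 lists together at percentile 5.28. The names stay open. A lack of difference between the sorted nuclei at these sites was not tested and stays open too. So does the part played by neuronal nuclei within the total group, which was not tested either.

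Whether the ric-19 peak draws on extra promoter copies in the reporter transgene stays open. The test asked for a fold over 2 times the next highest in both lists, and 1.95 and 1.84 times missed that, while its centred ratio of -0.04 lay within 1 SD of all shared peaks. The local background at ric-19 was itself 7.74 and 8.55 times the lowest of its list, so a fold over that background may miss extra copies. No nuclei without the transgene are in the series, so copies and open chromatin at the gene itself cannot be told apart. The peak near aex-5 (chromosome I from 14855378 to 14856268) had a pileup of 36951 in the list labelled neuronal, against 44027 for ric-19, but on a background of 2317 and with repeats or collapsed copies not analysed here. No biological explanation was tested.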
